A study of Drosophila melanogaster with 2 samples.

How the data were processed

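ChIP-seq peak lists of slbo-eGFP transgenic Drosophila melanogaster whole embryos, 8 to 24 h old, were analysed. Per the labels, chromatin was fragmented by sonication, the size range was 200 to 800 (no unit is stated), and the 2 samples were biological replicates 1 and 2 of the same line. The sample descriptions state precipitation with an antibody against GFP, while the antibody label reads slbo. The first was taken here, and with an antibody against Slbo the peaks would also include the untagged protein. They form 1 group, slbo-GFP embryo ChIP. The labels name a possible control experiment, which was not used here, so no background was measured the same way in embryos without the transgene.

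The deposited files were 8 peak lists on the dm6 genome, 4 thresholded (10 columns) and 4 ranked (20 columns). The lists of both kinds exist at the level of the series (called here series-level), as a conservative set of both replicates, and for each replicate alone. The aligner, peak caller, their settings and versions are not given in the sources used here. The signal column, in the deposited lists, is the peak caller's signal value, and it is not stated to be scaled for depth, so its size was compared only within a list, and between the replicates only as correlations. The score column was set by the authors from the irreproducible discovery rate (IDR), and its lowest value in the deposited thresholded lists is 830. The ranked lists give, per the file headers and the layout, the −log10 of the local and global IDR and the signals of the matched peaks in the lists compared, and those signals were not assigned to a replicate. Per the deposited descriptions, each thresholded list has a further parent file that the ranked list lacks. The lists give no read counts, so depth per sample is unknown, and precision is given as 95% Wilson intervals on shares of peaks, which cover counting error only.

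The series-level thresholded list of 8786 peaks was the main peak set, and each replicate's own thresholded list gave the values per replicate (mean and SD, n = 2). Peaks on the 6 arms 2L, 2R, 3L, 3R, 4 and X were used, 8714 of them, and peaks on Y and unplaced scaffolds were left out of the tests. Gene models were those of Ensembl release 115 on the same genome build, without transposable elements, and sequence was the RefSeq copy of that build. The position of a peak was its summit. A promoter was the region within 500 bp of any annotated transcription start site, and the other classes were assigned in the order 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron, intergenic.

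Overlap of the replicates was counted from 1 bp and compared with 1000 random placements of the peaks on the same arms (one-sided permutation test). Location classes were compared with 1000 sets of random positions on the same arms (two-sided permutation test, Benjamini-Hochberg adjustment over classes). Motif matches on either strand within 50 bp of the summit were compared with a window of 100 bp taken 400 to 500 bp to one side of the same summit, by exact McNemar tests. The main motif was TTRYRYAA, 16 8-mers of the C/EBP family, where R is A or G and Y is C or T. The rise between the lowest and highest signal quintile was tested with 100000 relabellings (two-sided permutation test). Every 8-mer in at least 10 windows was tested by Fisher's exact test with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a ratio of at least 1.5 in either direction. Gene lists were scored by the share of genes with a summit within 1 kb of a start site, against 10000 random lists of protein-coding genes of the same size and length deciles (two-sided permutation test, adjusted over 15 lists). Arms were compared with their share of the summed arm length by exact binomial tests, adjusted over 6 arms. The slbo locus was placed among all windows of 40 kb on 2R in steps of 1 kb.

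These tests, the gene lists, the motif and the rule for named genes were chosen before the data were examined, except for the 8-mers named individually, TATCGATA and its rearrangements, the gene families of the closing section and the composition checks, which were chosen after values had been seen. The rule names slbo, the 25 strongest peaks found in both replicates with the gene of the nearest start site, the 10 genes with most summits in the body or 2 kb upstream, and up to 4 members of each list by promoter peak signal. The lists covered border cell migration, bZIP factors, the JAK/STAT pathway, lipid and fat body metabolism, epidermis and cuticle, trachea, gut and Malpighian tubule, muscle, neurons and glia, hemocytes, the germ line, innate immunity, the ecdysone pathway, endoplasmic reticulum and amino acid stress, and ribosomal proteins. The list entries dp, dys, nos and phm were not matched by symbol or by a synonym of a single gene, because the annotation names these genes dpy, dysf, nanos and phtm. They were left out of the reported counts and added in an alternative chosen after the data were seen.

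Alternatives covered the peak set, each replicate alone, promoter and gene distances, motif windows and definitions, control windows, the overlap rule, list matching and the slbo window. The tests were also tested on simulated data. With no planted sites the motif test gave an exact p of 0.20, sites planted in 10.2% of windows gave an excess of 9.90%, and the 8-mer test called 0 of 32425 8-mers where nothing was planted. For the motif and 8-mer tests the simulated summits were random positions. Calls due to the base composition of real summit windows could therefore not show. Of 200 random gene lists 5 had an unadjusted permutation p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.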

Results

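The experiment was chromatin immunoprecipitation with sequencing (ChIP-seq) on whole Drosophila melanogaster embryos, 8 to 24 h old, that carried a transgene expressing Slbo fused to eGFP. Slbo (slow border cells, FBgn0005638) is the fly C/EBP protein, a basic leucine zipper (bZIP) transcription factor named for its role in border cell migration in the ovary. Protein and DNA were recovered with an antibody against GFP, as the sample description states, while the antibody label reads slbo. The 2 samples were biological replicates of 1 group, slbo-GFP embryo ChIP, and no control samples were analysed here. The series-level thresholded list of both replicates held 8786 peaks on the dm6 genome, 8714 of them on the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X). Replicate 1 alone had 7151 thresholded peaks and replicate 2 alone had 5445, a ratio of 1.31. The peak lists give no read counts, so the sequencing depth of each sample is unknown, and signal values of different lists were set against each other only as correlations, not in size. The intervals given with shares of peaks are 95% Wilson intervals, cover counting error only and treat neighbouring peaks as independent.

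The first question was whether the replicates bound the same places. They largely did: of the 7124 replicate 1 peaks on the arms, 4726 (66.3%, interval 65.2 to 67.4) overlapped a replicate 2 peak, and of the 5382 replicate 2 peaks, 4724 (87.8%, interval 86.9 to 88.6) overlapped a replicate 1 peak. Random placement on the same arms gave means of 2.24% and 2.94%, with maxima of 2.84% and 3.68%. The one-sided permutation p was 0.001 for both directions, the smallest that 1000 placements can give. Replicate 1 peaks that overlapped a replicate 2 peak had a median signal of 121.1, and those that did not had 55.7. In replicate 2 the medians were 88.0 and 47.8. Across the 4726 overlapping peaks, Spearman's rho between the signals of the replicates was 0.855 (bootstrap interval 0.844 to 0.865) and Pearson's r of log2 signals was 0.817. These correlations run across peaks, which are not independent replicates, so no p is given. Across all matched pairs of the ranked list, most of which fall under the threshold, rho was 0.439. Of the 8714 series-level peaks, 4683 (53.7%) overlapped a peak of both replicates and 1555 (17.8%) overlapped a peak of neither replicate alone, with median signals of 210 and 69.3.

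**Figure D1:**
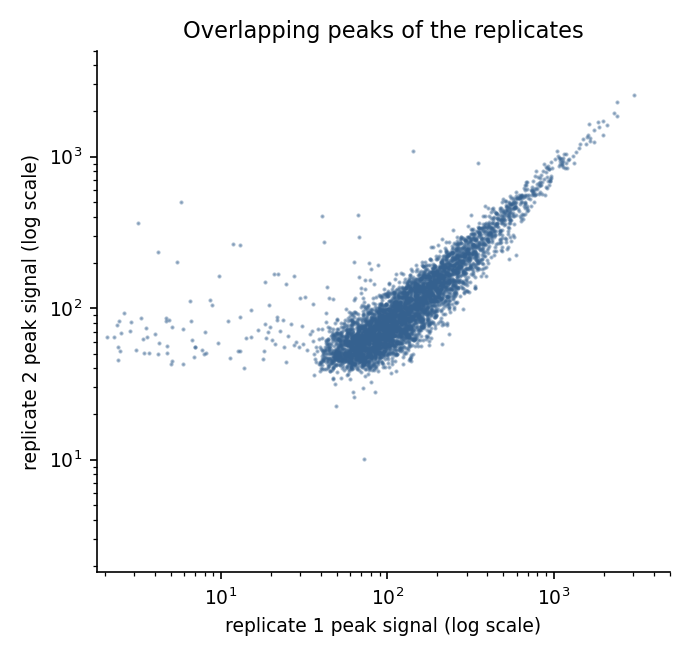
Signal of replicate 1 (horizontal axis, log scale) and replicate 2 (vertical axis, log scale) at the 4726 overlapping peaks, 1 point per peak. Most points follow a single band, with rho at 0.855.

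Most of the strongest peaks of the series-level thresholded list lay at promoters. The highest signal, 5564, was at the uncharacterised gene CG14100 (FBgn0036889; 3L, 19590433 to 19590808), 95 bp from its start site. It was followed by Ugalt (FBgn0024994; X, 2703708 to 2704082), which encodes a UDP-galactose transporter, with a signal of 4671. An intron of CG11050 (FBgn0031836; 2L, 6612537 to 6612905) had a signal of 4231. The promoter of mRpL41 (FBgn0034001; 2R, 15217568 to 15217990), a mitochondrial ribosomal protein, had a signal of 4161. The next peaks by signal were at Tcs5 (3695), at eIF6 (3676), a factor of ribosome maturation, at HmgZ (3534), a chromatin protein with an HMG box, at the transcription factor gene Adf1 (3398), at CG5611 (3350) and at the Polycomb group gene ph-p (3248). Signals between 2201 and 3215 were found nearest to Shc, Art3, CenG1A, CG8320, CG32772, mRpL23, PNPase, GstE13, Chro, CG7601, CG13390, CG9663, MFS10, CG13323 and gish. The Art3 and CenG1A peaks were also within 1 kb of the start sites of mRpS10 and mRpS23. Of these 25 peaks, 18 were in promoters, 6 in introns and 1 between genes, and 16 lay within 150 bp of a start site. All 25 ranked among the 50 highest in each replicate. Of the 25, only the CG13390 peak had a match to the C/EBP consensus TTRYRYAA within 50 bp of its summit. Among all series-level summits on the arms 5.34% had one, and 4.57% of their flanks. Peaks near cbt (4307) and Lk6 (2962), which the ranked list holds at a score of 830 or more but the thresholded list lacks, are not in this ranking.

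The second question was which parts of the genome were bound. Promoters held 4018 summits, 46.1% of all (interval 45.1 to 47.2), where a promoter is the region within 500 bp of an annotated transcription start site. Random positions on the same arms were in promoters 13.6% of the time, a ratio of 3.40. Introns held 35.3% of summits (39.4% of random positions) and intergenic sequence 13.9% (27.3%). Coding exons held 216 summits, 2.48% against 13.7%, and 3′ UTRs held 0.838% against 4.43%. For these 5 classes the adjusted permutation p was 0.0028, from the smallest p that the placements can give. The share in 5′ UTRs was lower than random, 0.539% against 0.783% (adjusted permutation p = 0.021), and that in exons of non-coding genes did not differ detectably, 0.838% against 0.814% (adjusted permutation p = 0.83). In the replicates' own lists the promoter share was 50.8% ± 0.861 (SD, n = 2) and the coding exon share 0.823% ± 0.0716 (SD, n = 2). The median distance from a summit to the nearest start site of a protein-coding gene was 788 bp, against 4281 bp for random positions, and 23.1% of summits were within 100 bp (random positions 2.80%). Stronger peaks were in promoters more often: the share was 30.1% in the lowest signal quintile, then 39.5%, 44.2% and 54.4%, and 62.2% in the highest. The rise of 32.1 percentage points had a permutation p of 1e-05, the smallest that 100000 relabellings can give.

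**Figure D2:**
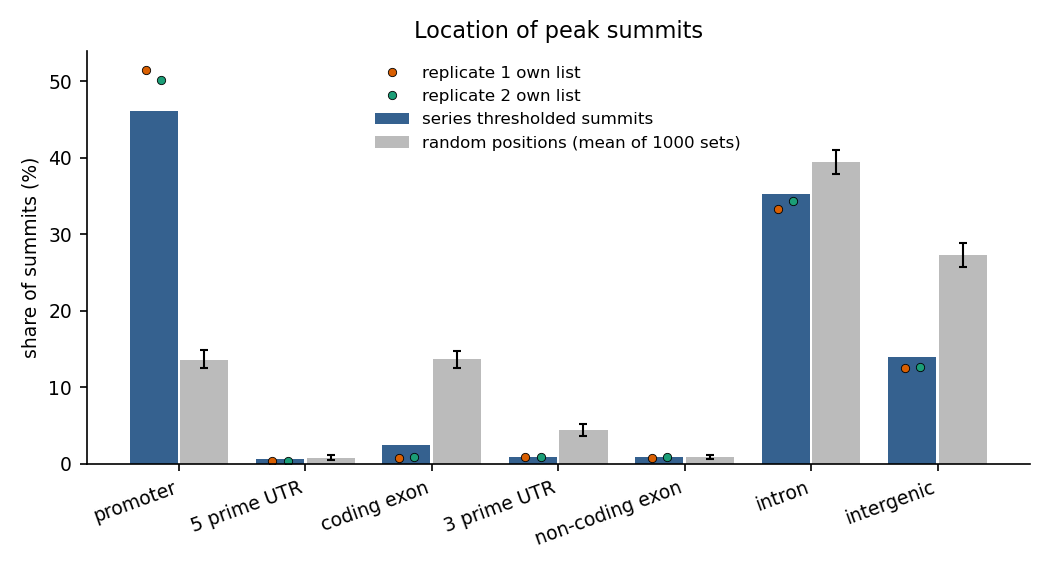
Share of summits (vertical axis, percent) in each annotation class for the series-level thresholded list (dark bars), the replicates' own lists (points) and random positions (grey bars, mean of 1000 sets, with error bars from the lowest to the highest set). Promoters hold 46.1% of summits and 13.6% of random positions, and coding exons 2.48% and 13.7%.

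Ranked peaks outside the thresholded list, called lower-ranked here, were in promoters less often than thresholded ones. Of the 117388 on the arms, 224 of which had a score of 830 or more, 14.2% were in promoters, against 46.1% of thresholded peaks. Among the next peaks in rank, as many as the thresholded ones, the share was 21.5%. The DNA replication-related element (DRE) core TATCGATA, bound by DREF and BEAF-32, was at 0.218% of all lower-ranked summits, against 2.38% of the thresholded ones (Fisher's exact p = 7.1e-113). Of the 207 thresholded summits with it, 195 were in promoters. The comparison was not matched on promoters, so it is not separate from the difference in promoter share. The C/EBP consensus TTRYRYAA was at 3.32% of lower-ranked and 5.34% of thresholded summits (Fisher's exact p = 1.6e-20). Of the 96 palindromic rearrangements of TTRYRYAA, itself included, 88 (91.7%) had a ratio of thresholded to lower-ranked summits at least as high as its 1.61. Lower-ranked summits were also poorer in A and T bases, 51.8% against 62.0%.

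Some genes carried many summits in the gene body or the 2 kb upstream. The gene with most was kirre (FBgn0028369; X, 2740384 to 3134532), an adhesion receptor of muscle founder cells, with 36 summits in 394 kb (31 in replicate 1, 23 in replicate 2). Next were Tlk (FBgn0283657; X, 3720007 to 3789770), a Tousled-like kinase, with 22 summits (16 and 9), CG1677 (FBgn0029941) with 21 (17 and 17), the nuclear protein gene sbb (FBgn0285917) with 20 (13 and 12) and bun (FBgn0259176), of the TSC22 family, with 18 (12 and 7). The forkhead gene CHES-1-like (FBgn0029504; 15 and 15), the zinc finger gene shn (FBgn0003396; 13 and 9) and the ecdysone-induced nuclear receptor gene Eip75B (FBgn0000568; 12 and 12) had 16 summits each. The Notch coactivator gene mam (FBgn0002643; 10 and 7) and CG32264 (FBgn0052264; 13 and 12) had 15 each. CHES-1-like is only 27.0 kb long and had 5.51 summits per 10 kb, against 0.909 in kirre. These are counts, with no test for gene length.

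The slbo gene itself lies on 2R (24331522 to 24334307, minus strand), and the transgene carries a tagged slbo, so its peaks were described apart. Within 20 kb of the gene there were 13 thresholded peaks, 1 inside it, 4 downstream and 8 upstream. Windows of 40 kb along 2R held 2.61 on average and 16 at most, which puts slbo at the 99.5th percentile. In the replicates' own lists 12 peaks each were found there, but they do not all match the 13. Those of signal 84.5, 74.6 and 52.5 had a counterpart in neither replicate's own list. That of 125 had one only in replicate 2, and that of 78.2 only in replicate 1. The strongest of the 13 had signals of 1386 (2R, 24327630 to 24327894, rank 84 in the list) and 1332 (2R, 24329445 to 24329708, rank 93). Both lay downstream of slbo in the non-coding gene lncRNA:CR44810. A peak of signal 685 (2R, 24343556 to 24343766) lay at bs (blistered), the fly serum response factor gene upstream. The peak at the start site of slbo (2R, 24334121 to 24334450) had a signal of 79.3, rank 6704, and was also in the list of replicate 1 but not in that of replicate 2. Peaks under the threshold were also stronger here than elsewhere on 2R, with a median signal of 44.2 within 10 kb of slbo against 24.3.

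**Figure D3:**
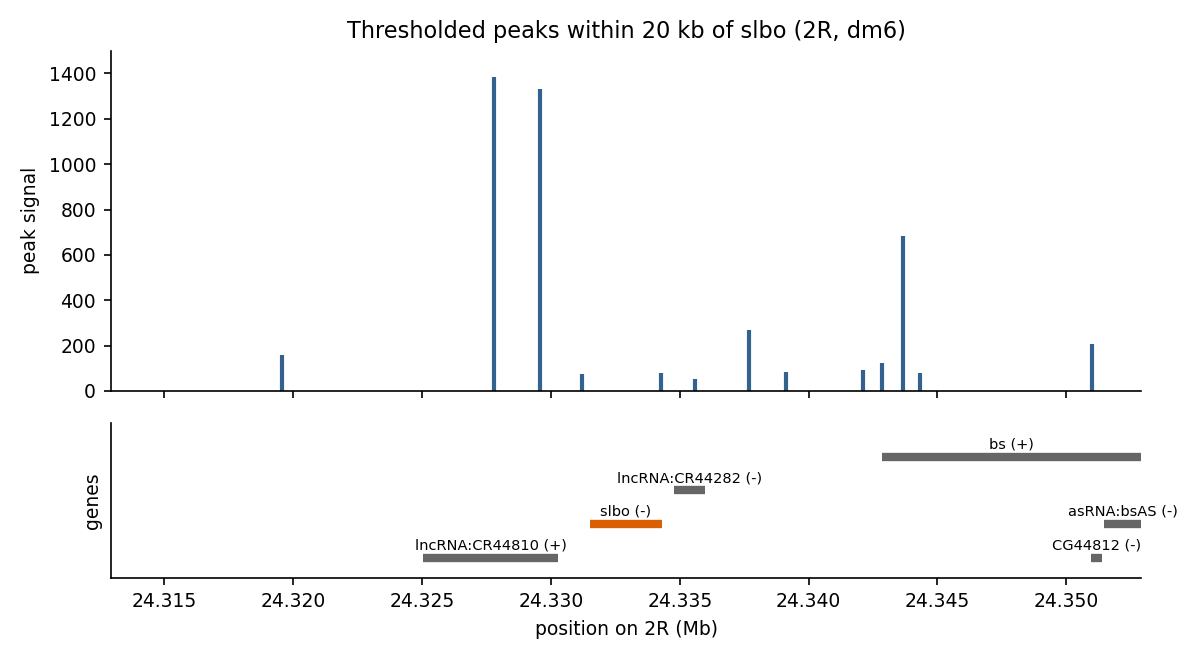
Signal of the 13 thresholded peaks within 20 kb of slbo (vertical axis) by position on 2R in Mb (horizontal axis), with the annotated genes and their strands below. The peaks of signal 1386 and 1332 lie in lncRNA:CR44810, and that of 685 at bs.

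The third question was which gene groups carried peaks at their promoters. Of 13945 protein-coding genes, 5080 (36.4%) had a thresholded summit within 1 kb of a start site (4762 in replicate 1 and 3720 in replicate 2). Genes of bZIP transcription factors, the family of Slbo, carried them more often than random lists: 17 of 21 (81%), slbo itself included, against 41.1% in lists matched on gene length (adjusted permutation p = 0.0090; replicates 69.0% ± 10.1, SD, n = 2). Examples were Atf3 (FBgn0028550), an ATF family factor, with a signal of 1752, REPTOR (FBgn0039209), a TORC1-regulated factor, with 1238, Xbp1 (FBgn0021872), of the unfolded protein response, with 561, and Pdp1 (FBgn0016694), a clock factor, with 464. So did ribosomal protein genes, 12 of 18 (66.7%) against 32.2% (adjusted permutation p = 0.036; the same count in each replicate), with RpL7 (750), RpL32 (597), RpL8 (437) and RpLP0 (351). The bZIP call was lost with a 500 bp distance (adjusted permutation p = 0.10), with nearest-gene assignment (0.26) and with gene bodies (0.078). The ribosomal call was lost with nearest-gene assignment (adjusted permutation p = 0.15) and without length matching (0.099).

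The genes of the cuticle and epidermis list carried promoter peaks in 3 of 17 cases (17.6%, random lists 50%), which missed the threshold (adjusted permutation p = 0.057). The 3 were Ddc (signal 112), an enzyme of cuticle sclerotisation, dsx-c73A (72.1) and Fas3 (64.1), the last with a promoter peak in neither replicate's own list. This list passed the threshold, below random lists, in the conservative peak set (adjusted permutation p = 0.019), with its unmatched member dpy added, which had no promoter peak (3 of 18, adjusted permutation p = 0.035), and in 4 further settings. The list missed the threshold within 500 bp (adjusted permutation p = 0.084), with nearest-gene assignment (0.26) and with gene bodies (0.24). Without length matching random lists had 36.4%, and it also missed the threshold (adjusted permutation p = 0.33). In the replicates its share was 8.82% ± 4.16 (SD, n = 2).

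No difference from random lists was detected for the other 12 lists, whose adjusted permutation p ran from 0.48 to 1. Border cell migration, the process for which slbo is named, had 12 of 22 genes (54.5%, random lists 48.9%), among them apt (556), mbc (508), tai (436) and aop (381). Lipid and fat body metabolism had 13 of 20 genes (65.0%, 45.7%), with Lpin (882), bmm (547), SREBP (284) and fbp (215). Endoplasmic reticulum and amino acid stress had 10 of 17 (AsnS 727, Xbp1 561, Ire1 520 and Herp 496), and innate immunity 10 of 18 (imd 967, cact 476, PGRP-LB 431 and dl 160). Muscle had 10 of 18 genes (sls 511, tin 477, Mef2 201 and if 156) and the gut and Malpighian tubule 7 of 18 (bowl 842, Vha16-1 368, lin 184 and fkh 135). Neurons and glia had 6 of 18 (moody 2000, elav 1147, nrv2 148 and fne 107), the ecdysone pathway 6 of 17 (usp 262, Hr78 218, EcR 170 and Eip75B 153.03) and the germ line 6 of 13 (orb 801, piwi 414, bgcn 347 and vas 177). Trachea had 5 of 17 (crb 350, trh 220, pnt 128 and rib 103), hemocytes 5 of 17 (ush 429, Hml 256, Col4a1 83.6 and SPARC 72.5) and the JAK/STAT pathway 5 of 12 (Stat92E 297, Ptp61F 239, Su(var)2-10 144 and Socs36E 102). Adding members that were not matched by symbol, nanos (342) would make the germ line 7 of 14 and dysf (146) would make the trachea 6 of 18, while phtm of the ecdysone pathway had no promoter peak. Some members counted as lacking a peak had one in the ranked list with a score of 830 or more. With all ranked peaks of that score border cell migration had 14 of 22 genes (adjusted permutation p = 0.44). Endoplasmic reticulum and amino acid stress had 12 of 17 (adjusted permutation p = 0.20). The gut, immunity and ecdysone lists also gained members, and the 12 lists stayed short of the threshold. In the replicates' own lists (replicate 1, then replicate 2) the counts were 7 and 5 for muscle, 5 and 4 for the gut and Malpighian tubule, 6 and 3 for neurons and glia, 2 and 3 for hemocytes, and 5 and 3 for the JAK/STAT pathway. Of the genes named here, rib and SPARC had a promoter peak in neither replicate's own list. The numbers after the gene names are the signals of their strongest promoter peaks in the series-level list.

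**Figure D4:**
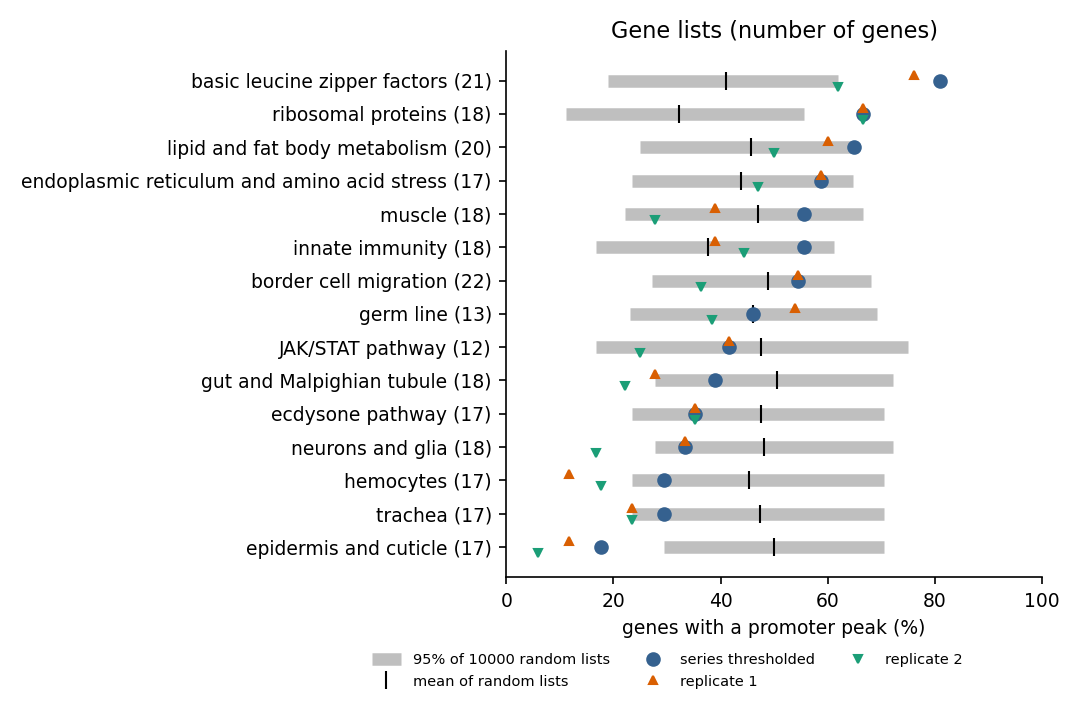
Share of the genes of each list with a promoter peak (horizontal axis, percent) in the series-level list and in each replicate, with the mean and the middle 95% of 10000 random lists matched on gene length. The bZIP list is at 81% and the ribosomal list at 66.7%.

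The fourth question was whether summits held the binding site of the C/EBP family, TTRYRYAA. Within 50 bp of the summit 465 peaks had it (5.34%, interval 4.88 to 5.83), and in flanks of the same width 400 to 500 bp away 398 had it (4.57%), a ratio of 1.17 (exact McNemar p = 0.020). The ratio missed the threshold in the conservative set, with 25 bp windows, with matched random positions and with the other flank (exact McNemar p from 0.056 to 0.51). It passed in the other alternatives with TTRYRYAA. In the replicates' own lists the shares were 5.81% ± 0.432 (SD, n = 2) at summits and 4.35% ± 0.0356 in flanks. Outside promoters the shares were 6.05% and 4.98% (exact McNemar p = 0.025), in promoters 4.50% and 4.08% (exact McNemar p = 0.38), and the difference between these places was not tested. The perfect palindrome TTGCGCAA was at 13 summits and 19 flanks (exact McNemar p = 0.38). The relaxed site TTRCNNAA was at 17.2% of summits, a ratio of 1.26 to flanks (exact McNemar p = 6.4e-11), and its rearrangements were not tested. Among the signal quintiles, the share of TTRYRYAA was 3.96% in the lowest and 6.08% in the highest (permutation p = 0.0052), and it fell short of the threshold in each replicate's own list (permutation p = 0.24 and 0.21). Summit windows were richer in A and T than flanks, 62.0% against 57.0%. Of the 96 palindromic rearrangements of the bases of TTRYRYAA, itself included, 84 (87.5%) had a ratio of summits to flanks at least as high, and 91 (94.8%) had a rise with signal at least as large.

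**Figure D5:**
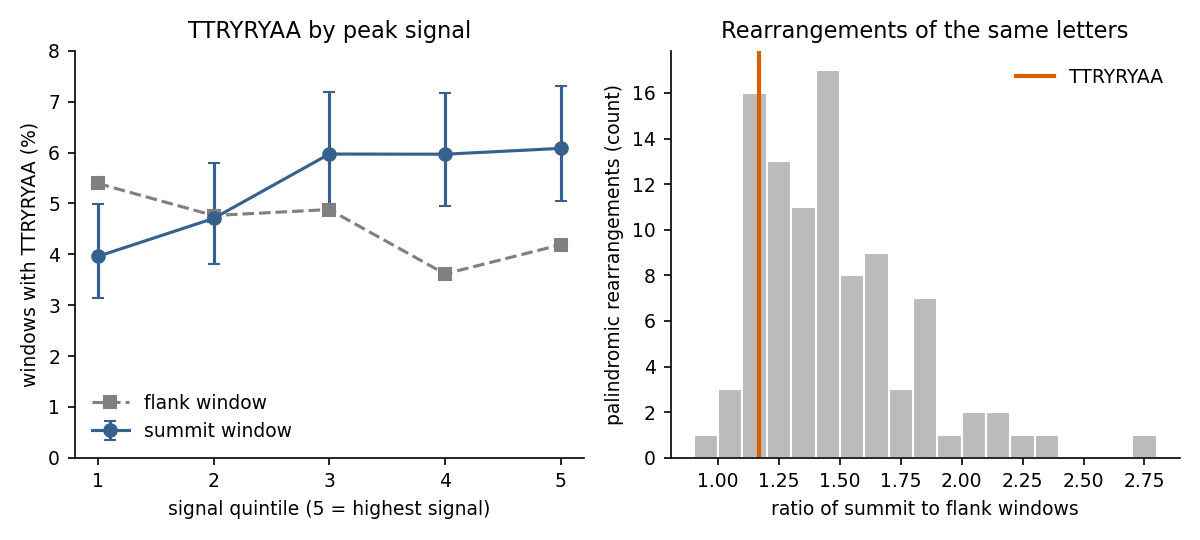
Left, share of summit and flank windows with TTRYRYAA (vertical axis, percent) by signal quintile (horizontal axis, 5 is the highest); bars are 95% Wilson intervals, and the summit share goes from 3.96% to 6.08%. Right, number of the 96 palindromic rearrangements of TTRYRYAA (vertical axis) by ratio of summit to flank windows (horizontal axis), with TTRYRYAA itself marked at 1.17.

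A different site, chosen after its values were seen, stood out at promoters. The DRE core TATCGATA was at 207 summits (2.38%) and in 29 flanks (0.333%), a ratio of 7.14 (exact McNemar p = 4.7e-35). Its share in the replicates' own lists was 2.63% ± 0.828 (SD, n = 2). From the lowest to the highest signal quintile its share was 0.803%, 2.70%, 3.04%, 3.33% and 2.01%. Of the 25 strongest peaks named above, 0 had it. In promoters 195 summits had it (4.85%, flanks 0.548%), and outside promoters 12 had it against 7 flanks (exact McNemar p = 0.33). It was not compared with promoters that lack a peak. Of the 64 palindromic rearrangements of TATCGATA only itself reached its ratio, and the next highest was 4.50. It was chosen on these same windows, so this is no independent test, and a test on arms where it was not chosen is given in the closing section. Among all 8-mers, 32216 were tested, of which 884 were called enriched at summits and 616 depleted, by Fisher's exact test. TATCGATA was first, followed by ATCGATAG (2.80% of summits, 0.528% of flanks) and ATATTTTA (4.50%, 1.71%). In the replicates' own lists TATCGATA was second in replicate 1 and at rank 19 in replicate 2, and it was at rank 8 in the upper part of the series-level list by signal and at rank 6 against lower-ranked summits. Enriched and depleted 8-mers numbered 1449 and 1453 in replicate 1, 984 and 727 in replicate 2, and 4957 and 6940 against lower-ranked summits. Which of the 2 was larger thus depended on the setting. CAACACTG (1.76%, 0.356%) and CAGCCCTG (1.06%, 0.149%) were also called, as was GGTCACAC (1.20%, 0.264%), the Motif 1 core of promoters bound by M1BP. The most depleted by rank was CAACAACA (1.01%, 2.74%). None of the 10 tested 8-mers that match TTRYRYAA was called. The best of them, TTACACAA, had a ratio of 1.8 (adjusted Fisher exact p = 0.070). TTATACAA (67 summits, 42 flanks) and TTACATAA (77, 56) were also more frequent at summits. Those ending in GCAA showed no such excess: TTGCGCAA was at 13 summits and 19 flanks, TTACGCAA at 23 and 29, TTGCACAA at 55 and 65, and TTATGCAA at 64 and 63. This grouping was made after the counts were seen. Of the 884 enriched 8-mers, 652 had at least 6 A or T bases, against 4776 of the 32216 tested and 13 of the 616 depleted.

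Along the genome, chromosome 4 was nearly free of peaks. It carried 10 thresholded peaks, 7.42 per Mb, 0.114 times its share of the arm lengths (adjusted exact binomial p = 6.9e-25), with 13 in replicate 1 and 4 in replicate 2. The X had 70.2 peaks per Mb, 1.08 times its share (adjusted exact binomial p = 0.0023), and 3R had 61.8, 0.950 times its share (adjusted exact binomial p = 0.018). The other 3 arms, 2L, 2R and 3L, held between 65.1 and 66.6 peaks per Mb and did not pass the threshold. The directions on 4, X and 3R were the same in each replicate's own list. Arms were not recounted with the 224 peaks of score 830 or more that the thresholded list lacks. The strongest of these, near cbt, lay on 2L, and the next, near Lk6 and larp, on 3R. The replicates' thresholded lists were likewise shorter than their ranked lists at that score (7151 against 7360, and 5445 against 5663). Whether the low share of 3R depends on the absent peaks was therefore not tested.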

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

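The test of shoulders of strong peaks was chosen before its result was seen, and the other tests of this part were chosen after.

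Peaks under the threshold were raised at slbo: the 19 within 10 kb of the gene had a median signal of 44.2, against 24.3 for the 22421 on all of 2R. The signal lies outside the thresholded peaks on which the report rests. In the replicates' own lists the medians were 27.4 against 14.4 in replicate 1 (17 peaks near slbo) and 18.5 against 14.4 in replicate 2 (22 peaks). The rise was smaller in replicate 2, and the replicates were not placed among windows. The slbo median was at the 99.99th percentile of 9454 windows of 20 kb on 2R, a value that extra copies of the region carried by the transgene may give, and which stays open because no input or copy number was measured. Among windows on all 6 arms away from slbo, 0.595% of the 168 with as many thresholded peaks had as high a median, which argues against dense binding. Of the 774 with as high a thresholded peak, 0% did. These were matched on their highest peak alone, while peaks of signal 1386 and 1332 both lie near slbo, so shoulders of strong peaks stay open. Of the bins around slbo, the one with both peaks (2R, 24325415 to 24330414) had the highest median under the threshold, 75.1 from 3 peaks. All windows were taken every 2 kb and overlapped, so the percentile and the shares count the same places repeatedly and are coarse.

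The ranked series-level list held 280 peaks with a score of 830 or more that the thresholded list lacks, 224 of them on the arms. Their median signal was 132, against 121.2 for those kept, and the strongest was near cbt (2L, 480894 to 481275) with a signal of 4307, followed by Lk6 (2962) and larp (1925). These peaks lay in runs: 125 neighbouring pairs were within 10 kb of each other with 1 kept peak between them in all, against 10.5 pairs on average and 23 at most in random draws, with 8.39 kept peaks between them. The most were nearest to ATbp (22 peaks), tara (13) and Kdm2 (8).

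Of the thresholded peaks, 72 lay on the Y or on unplaced scaffolds, outside the tests of the report, on 50 sequences, with a median signal of 104 and a highest of 1100.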

How the results depend on the processing

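The alternatives with the other flank, with 1 peak per group of overlapping peaks, with all ranked peaks of score 830 or more, with 4 renamed list entries added, those at the slbo locus other than its width, the lower-ranked comparison in each replicate, the correlation at that score, and all ranks and summit counts of named genes were chosen after the data had been seen. The promoter share, the replicate overlap, the peaks per arm and the comparison with lower-ranked peaks kept their direction and their side of the threshold under every alternative run for them; without either replicate the promoter share was 50.2% to 51.4%. Overlap and correlation need both replicates, so leaving one out was not possible for them. The C/EBP ratio of 1.17 missed the threshold in the conservative set (1.10, exact p = 0.17), with 25 bp windows (1.07, exact p = 0.51), with matched random positions (1.14, exact p = 0.056) and with the other flank (1.11, exact p = 0.11), and turned to 0.684 for TTGCGCAA (exact p = 0.38). It passed, at 1.16 to 1.42, in the 5 other alternatives with TTRYRYAA and, at 1.26, with TTRCNNAA; without either replicate it was 1.26 to 1.41. Its rise with signal missed the threshold in the upper part of the list by signal (0.229 points, permutation p = 0.92) and in each replicate's own list (1.05 to 1.39 points). Enriched 8-mers numbered 984 to 1449 in each replicate's own list and 4957 against lower-ranked summits. Depleted ones numbered 951 in the upper part of the list by signal, 727 to 1453 in each replicate and 6940 against lower-ranked summits. The number of called gene lists, 2 as reported, was 1 with 500 bp, with gene bodies and without length matching, 0 with the nearest gene, and 3 in each replicate's own list and with the renamed entries. The slbo percentile was 99.8 with 10 kb, 94.3 with 50 kb, 99.8 in the conservative set and 99.7 to 99.9 in each replicate's own list. The rank correlation was 0.439 over all matched ranked pairs and 0.843 over those with a score of 830 or more. For single named genes, lists and arms, 126 values under alternatives stayed on the same side of their test, within 1.5 times or, for peak ranks, among the 50 highest, 6 list tests newly passed the threshold (epidermis and cuticle under 6 alternatives, below random lists), 5 no longer passed it (bZIP and ribosomal), and 7 counts of summits at kirre, Tlk, sbb, bun, shn and mam in replicate lists moved by over 1.5 times, to between 7 and 23. The cause was not tested for any of these. Depth is unknown, so its limit on the number of peaks could not be measured.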

Other observations

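The gene families, the base composition tests of TTRYRYAA and TATCGATA, and the neighbour-matched expectation for families other than mitochondrial ribosomal proteins were chosen after results had been seen. The tests of higher-signal peaks outside promoters and of other start sites close by were chosen before.

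Among 20 gene families defined by gene symbol, promoter peaks were frequent in some families of basic cell functions and rare in those of sense organs, detoxification and cuticle. Mitochondrial ribosomal protein genes had them in 51 of 73 cases (69.9%, length-matched random lists 23.3%; replicates 57.5% ± 15.5, SD, n = 2), with mRpL41 (signal 4161), mRpS10 (2996, a peak shared with Art3), mRpS23 (2983, shared with CenG1A) and mRpL23 (2915). Cytosolic ribosomal protein genes had them in 70 of 92 cases (76.1%, random 28.3%), aminoacyl-tRNA synthetase genes in 22 of 35 (62.9%, 41.1%), nucleoporin genes in 15 of 21 (71.4%, 41.7%) and autophagy genes in 14 of 20 (70%, 42.2%). At the low end were ionotropic receptors 1 of 60 (1.67%, random 37.3%), Tweedle and Osiris genes 1 of 50 (2.00%, 30.4%), odorant receptors 3 of 59, gustatory receptors 5 of 60, odorant-binding proteins 4 of 51, Cpr cuticular proteins 4 of 70 (5.71%, 28.8%), Cyp genes 11 of 85 (12.9%, 37.9%) and Ugt genes 5 of 35. These 5 families above and 8 below random lists passed the threshold, with adjusted permutation p from 0.0005 to 0.030, and the other 7, among them proteasome, respiratory complex I and eIF genes, did not. With lists matched also on a neighbouring start site within 1 kb, the synthetases, nucleoporins, autophagy genes and Ugt genes no longer passed it (adjusted permutation p from 0.17 to 0.38). In replicate 2's own list the share was 42.9% for nucleoporins, 2.86% for Cpr, 5% for gustatory receptors, 8.24% for Cyp and 8.57% for Ugt genes, and for odorant-binding proteins it was 3.92% in each replicate's own list. The families were not tested in the replicates' own lists.

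The peaks at mitochondrial ribosomal protein genes were weighed further. The family was singled out after some of its genes were seen among the strongest peaks, so its share of 69.9% is no independent test. Peaks that belong to other genes with a start site close by could add to their share. Lists matched on length and neighbouring start sites gave 35.7%, still below 69.9% (permutation p = 0.0002, the smallest that the lists can give). The presence of a neighbouring start site alone thus did not account for the share, though the p carries the choice of the family on these same peaks. The lists were not matched on whether the neighbour was itself bound, so peaks of neighbours stay open as a source. No biological explanation was tested for this family.

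Since summit windows were richer in A and T than flanks, the C/EBP and DRE sites were weighed against base composition: for TTRYRYAA, 87.5% of the palindromic rearrangements of its bases had a ratio to flanks at least as high, 94.8% a rise with signal at least as large and 91.7% a ratio to lower-ranked summits at least as high, so composition may account for all 3 results. TATCGATA led all 8-mers, so it was chosen again on 2L and 2R alone, as the most enriched palindromic 8-mer with a G or C base, and tested on the other arms. There 3.12% of its 64 rearrangements had a ratio at least as high as its 5.98, with 0.5 added to each count (the highest other 6.33, median 1.30). This argues against composition as the whole source. Most summits with TATCGATA lay in promoters and the controls were flanks, so an excess over other promoters was not tested. A hypothesis that C/EBP sites sit in the stronger peaks outside promoters was tested in the 1920 strongest by signal: the ratio was 1.51, but 72.9% of rearrangements had one at least as high. These tests leave open whether a minority of peaks holds C/EBP sites, and no control ChIP was used that could separate peaks of other origin.

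In the series-level list, 535 of 8714 peaks (6.14%) overlapped another peak of the same list. Of the 189 peaks with a signal under 35, 181 (95.8%) did.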
